A study of Homo sapiens with 24 samples.

How the data were processed

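The series holds paired gene expression and surface protein libraries of bone marrow mononuclear cells from 12 patients with acute myeloid leukaemia and abnormalities of chromosome 7, 24 samples in all. In this assay (CITE-seq) cells are stained with antibodies that carry DNA tags, so that the RNA and the bound antibodies of one droplet are counted under one cell barcode. The labels name the kind of library and a patient number, and give no contrast between patients and no healthy control. Comparisons were therefore made within patients between classes of cells, with T-like cells as the reference for chromosome 7.

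Gene expression values are raw UMI counts (distinct RNA molecules) per gene and barcode that the authors deposited, made with Cell Ranger 3.1.0 on GRCh38 per the submitters' processing notes, over 33538 genes. Antibody values are raw tag counts per antibody and barcode as deposited. The tool behind them, and whether they count molecules or reads, are not given in the sources used here. The deposited tables list 31 antibodies and an unassigned category, while the design text speaks of 32, and no isotype control antibody is among them. Between 4.34% and 18.5% of a library's tags were unassigned (median 7.79%). These were left out of all sums.

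The RNA libraries held 39432 barcodes and 206032104 UMIs, from 5778076 to 29725740 per library. Cells with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs were kept, 32637 in all. Scrublet marked 129 of them as doublets, 0.395%, a share at which the caller has not worked, so most doublets must be taken to remain. Removing those 129 left 32508 cells. The median cell of a library had 2558 to 9361.5 UMIs. Of the analysed cells, 27558 (84.8%) had an antibody barcode, 29.8% to 99.4% per library, with a median of 180 to 3176 tags per cell. Pairing of RNA and antibody libraries was checked through their barcodes, and 0 libraries failed to match their labelled partner. The 12 patients are taken as separate donors from the labels.

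Cells were clustered jointly with scanpy 1.11.5 (2000 variable genes, 40 principal components, 20 neighbours, Leiden clustering with igraph 0.11.9 at resolution 1.5). Genes of chromosomes 7, X and Y, and mitochondrial, ribosomal and variable receptor genes were kept out of the clustering. So were genes of the lists tested later, unless they were cell type markers. A cluster took the name of a class from fixed marker genes when at least 3 markers were detected in at least 10% of its cells and at 2-fold over other clusters. Clusters whose leading genes contradicted the name stayed unnamed. Of 38 clusters, 13 were progenitor-like, and 10 of these had more than 10 cells in 1 patient only. The progenitor-like class joins stem-like and granulocyte-monocyte progenitor-like clusters and does not separate leukaemic from healthy cells. Markers and classes come from the same cells, so markers and clustering genes were not named as differences in RNA between classes, and counts of called genes are given without them and, where said, with them. For other genes that vary with the clustering genes, p-values between classes are too small for the same reason.

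Chromosome 7 expression was measured per patient and class with at least 20 cells. Counts were summed and scaled to CPM, and the log2 ratio to T-like cells of the same patient was taken for genes with a mean of at least 50 CPM, with a pseudocount of 5. The median over chromosome 7 genes minus the median over autosomal genes is the reported value. Gene positions came from GENCODE 29 on GRCh38, the arms were split at position 60000000, and T cell receptor genes were left out. Means over patients were tested with an exact two-sided sign-flip permutation test. Benjamini-Hochberg adjustment ran over 22 autosomes and, separately, over the 5 classes. For single cells, counts were thinned to 1500 UMIs, and a cell was called low when its chromosome 7 share was under 0.75 times the median of T-like cells of its patient.

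Genes were tested on counts summed per patient and class with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, patient as block, Benjamini-Hochberg threshold 0.05). The block rests on the donor: both classes of a pair come from the same library. Fold changes are log2 with their standard errors (SE), computed from the fold change and the F statistic of the test. A set of 15 gene lists, fixed in advance, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Antibody counts were summed likewise, turned into centred log2 ratios with a pseudocount of 1, and compared by sign-flip tests with adjustment over 31 antibodies. Correlations of antibodies with RNA or with chromosome 7 share were Spearman coefficients over the progenitor-like cells of each patient with at least 50 such cells, tested over patients.

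Named genes were all measured members of the chromosome 7 lists, the BCL2 family list and the AML surface target list, the 5 chromosome 7 genes with the largest rise and the 5 with the largest fall among those past the threshold that moved one way in at least 80% of patients, and for each other list the 2 members with the smallest p in each direction. Sex chromosome genes, variable receptor genes and some HLA and null-allele genes were never named. These rules, the tests, the lists and the first set of alternatives were set before the data were examined. The alternatives covered normalization and DESeq2 1.42.0, low-count filters, the block, cell filters, doublets, class assignment, minimum cell numbers, chromosome 7 measures, thinning, and leaving out each patient.

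The methods were tested on simulated data. For 8776 genes drawn after the comparison of progenitor-like with T-like cells, edgeR recovered 57.7% of 2-fold and 100% of 4-fold changes, and 6.00% of its calls were false. For 9206 genes drawn after the comparison of monocyte-like with progenitor-like cells, the shares were 52.5%, 96.8% and 8.86%. Simulated chromosome 7 ratios of 1, 0.75 and 0.5 between progenitor-like and T-like cells came back as 0.983, 0.767 and 0.514. The other differences between classes were drawn without regard to chromosome. This simulation therefore cannot tell whether the measure separates chromosome 7 loss from differences between cell types. Values of single patients are given without any patient number.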

Results

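Single-cell RNA and surface protein were measured together in bone marrow mononuclear cells from 12 patients with acute myeloid leukaemia whose cells carried abnormalities of chromosome 7. Each patient contributed 1 RNA library and 1 antibody library. The RNA libraries held 5778076 to 29725740 UMIs, and the antibody libraries held 1728743 to 30208552 tags. After filtering, 32508 cells were analysed, of which 27558 also had antibody counts. The labels define no groups of patients, so every comparison below was made between classes of cells from the same patients. The spread given is that between patients unless stated, except for fold changes of genes, which carry an SE.

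Progenitor-like cells, named from stem and granulocyte-monocyte progenitor markers, had the highest mean share, with 36.5% ± 32.5 of cells (SD, n = 12). Erythroid-like cells made up 27.5% ± 28.98, B-like cells 9.17% ± 23.2, T-like cells 8.86% ± 7.29, mast and basophil-like cells 5.40% ± 14.4, monocyte-like cells 4.95% ± 7.92 and NK-like cells 3.90% ± 6.00. In the same order from progenitor-like to NK-like cells, the medians over patients were 23.3%, 13.9%, 1.98%, 7.92%, 0.405%, 2.31% and 1.10%. At least 20 mast and basophil-like cells were found in 4 patients, and at least 20 B-like cells in 8. Plasma-like and megakaryocyte-like cells were rare, at 0.583% ± 0.745 and 0.354% ± 0.423, and 2.84% ± 6.48 of cells stayed unnamed. When each cell was assigned by its own marker score, progenitor-like cells made up 25.6%, erythroid-like cells 25.3%, plasma-like cells 2.43% and megakaryocyte-like cells 3.29%. The spread between patients was as large as the mean for most classes, and shares depend on which cells survived isolation, so no order between classes was tested.

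Chromosome 7 genes were expressed at a lower level in progenitor-like than in T-like cells. The mean chromosome 7 value was -0.44 ± 0.39 on the log2 scale (SD, n = 10 patients), a ratio of 0.736, and it lay below 0 in 7 of 10 patients. Monocyte-like cells had -0.41 ± 0.44 (n = 9) and erythroid-like cells -0.23 ± 0.37 (n = 10). The lymphoid classes lay close to T-like cells, with -0.04 ± 0.08 in NK-like cells and 0.04 ± 0.08 in B-like cells (n = 8 each). The NK-like class may hold T cells, which was not tested. Its mean of patients' median CD3 antibody tags was 77.4 ± 84.1 (SD, n = 7), against 166 in T-like and 14.1 in B-like cells. The NK-like value is therefore not a reference separate from T-like cells. T-like cells split at random gave 0.00 ± 0.05.

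For progenitor-like cells the exact sign-flip permutation test gave p = 0.0156, adjusted p = 0.0382 over 22 autosomes and adjusted p = 0.0781 over the 5 classes. For monocyte-like cells the exact permutation p was 0.0313, adjusted p = 0.0859 over autosomes and 0.0781 over classes, and for erythroid-like cells it was 0.0801. Neither passed after adjustment, and over the 5 classes no class did. No difference between classes passed adjustment over 10 pairs either. Progenitor-like cells differed from NK-like cells by -0.45 ± 0.38 and from B-like cells by -0.38 ± 0.37, lower in 6 of 7 patients each (exact permutation p = 0.0469, adjusted p = 0.166 for both), and from monocyte-like cells by -0.08 ± 0.26 (n = 9, exact permutation p = 0.457).

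Chromosome 7 was not the only chromosome to differ between these cell types. In progenitor-like cells 12 of 22 autosomes passed the adjusted threshold, 5 with lower and 7 with higher values than T-like cells. Chromosome 7 had the lowest mean of the 22 and was the lowest in 6 of 10 patients. Chromosome 16 followed with -0.24 ± 0.24 and was below 0 in 10 of 10 patients (exact permutation p = 0.00195, adjusted p = 0.0143). Chromosome 21, with 27 genes, had the highest mean at 0.51 ± 0.43. The call for chromosome 7 also depended on the measure: a ratio of summed UMI shares gave -0.34 (exact permutation p = 0.160), and a stricter cell filter gave -0.40 (n = 8, exact permutation p = 0.0547). As a ratio of summed UMI shares, chromosome 7 had only the 3rd lowest mean of the 22.

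**Figure D1:**
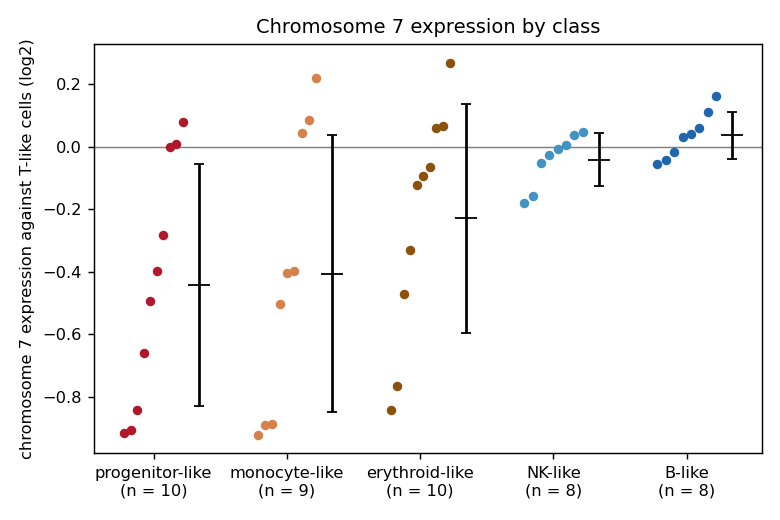
Chromosome 7 expression of each class against T-like cells of the same patient (log2, vertical axis), with 1 point per patient in rising order and the mean ± SD beside it. Progenitor-like values spread from -0.92 to 0.08 and monocyte-like values from -0.92 to 0.22, while NK-like and B-like values lie between -0.18 and 0.16.

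**Figure D2:**
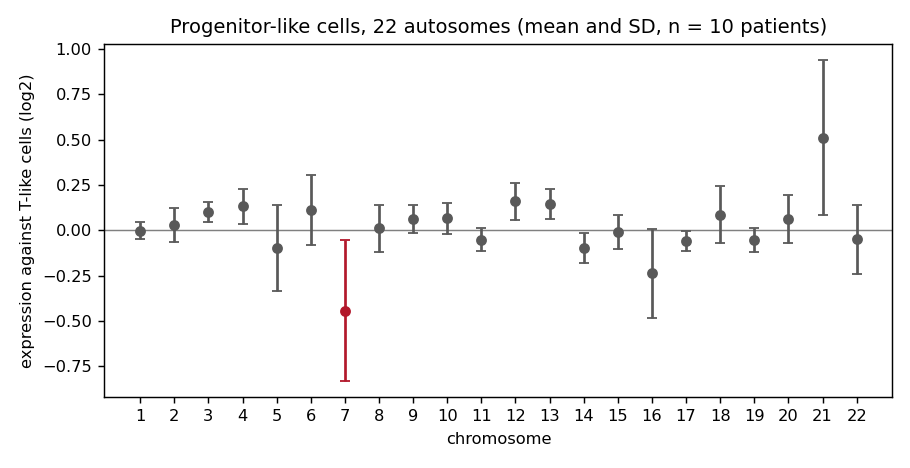
Mean ± SD over 10 patients of the expression of each of 22 autosomes (horizontal axis) in progenitor-like against T-like cells (log2, vertical axis). Chromosome 7, in red, has the lowest mean at -0.44, and chromosome 21 has the highest at 0.51.

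Split by arm, the lower level passed the test on the long arm. In progenitor-like cells the 66 genes measured on 7q had a value of -0.62 ± 0.38, a ratio of 0.649, and it was below 0 in 10 of 10 patients. The 44 genes on 7p had -0.18 ± 0.47 and were below 0 in 6 of 10. The permutation p was 0.00195 for 7q, the smallest that 10 patients allow, and 0.258 for 7p; adjusted over 15 tests of arms in 5 classes these were 0.0293 and 0.430. The arms differed by -0.44 ± 0.37 (permutation p = 0.00781, adjusted p = 0.0586), which did not pass adjustment. With a ratio of summed UMI shares this difference was 0.02, and with the more highly expressed genes alone it was -0.08. The 7p value was -0.36 and -0.35 with these, and neither passed (permutation p = 0.197 and 0.0801). The 7q value itself was -0.33 as such a ratio (permutation p = 0.0977) and -0.27 when ribosomal protein genes were also left out (permutation p = 0.0547), so its call was lost with both. In monocyte-like cells 7q had -0.56 ± 0.48 (n = 9, exact permutation p = 0.0156, adjusted p = 0.0781) and 7p -0.27 ± 0.54.

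At the level of single cells, 39.2% ± 45.2 of progenitor-like cells were low in chromosome 7 expression, against 12.9% of T-like cells of the same 9 patients. The difference of 26.3 ± 45.8 points was positive in 6 of 9 patients and did not pass the exact permutation test (p = 0.191, adjusted p = 0.319). Monocyte-like cells had 30.9% low cells (n = 8, a difference of 18.8 points, exact permutation p = 0.258), B-like cells 14.7% and NK-like cells 3.87%. The median over patients was 17.8% in progenitor-like and 7.92% in monocyte-like cells. Other autosomes gave differences from -18.3 to 49.8 points in progenitor-like and from -11.7 to 36.1 points in monocyte-like cells, so larger ones than that of chromosome 7 occurred. Erythroid-like cells had 82.5% ± 15.6 against 12.7% in T-like cells (n = 8, exact permutation p = 0.00781, adjusted p = 0.0391). The same measure applied to the other autosomes gave a median difference of 64.6 points in erythroid-like cells, and haemoglobin genes took a mean of 52.0% of their UMIs. Low cells are defined by a limit on a score, and whether they form a type was not tested. Within 0.05 of the limit lay 338 of the 9117 progenitor-like cells compared and 247 of the 2547 T-like cells.

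Among the listed chromosome 7 genes tested, HOXA9, HOXA7 and HOXA10 had the largest differences between progenitor-like and T-like cells. The listed HOXA3, HOXA5 and HOXA6 were not tested here. HOXA9, a homeobox factor of stem and progenitor cells, was higher in progenitor-like cells by 5.45 ± 0.37 (log2 ± SE) in 10 of 10 patients, HOXA7 by 4.71 ± 0.41 and HOXA10 by 4.21 ± 0.42. HOXA9 (ENSG00000078399, 7p, chromosome 7 from 27162435 to 27175180 on GRCh38) had 127 ± 78.6 CPM in progenitor-like and 1.69 ± 2.02 CPM in T-like cells (SD, n = 10). On 7q, CDK6, a cell cycle kinase, was higher by 2.36 ± 0.20, IRF5 by 2.70 ± 0.46, CUX1 by 1.36 ± 0.21 and TRIM24 by 1.32 ± 0.23. CDK6 (ENSG00000105810, 92604921 to 92836594) had 290.3 ± 198.6 CPM against 49.9 ± 26.3. In the other direction, SAMD9 (-1.38 ± 0.25) and SAMD9L (-1.36 ± 0.36), 7q genes that restrain growth, were lower, as were KMT2E (-1.12 ± 0.19), SBDS, needed for ribosome assembly (-1.22 ± 0.21), ARPC1B (-1.41 ± 0.26), CUL1 (-0.96 ± 0.26) and CNOT4 (-0.53 ± 0.20). On 7p, IKZF1, a lymphoid transcription factor, was lower (-1.11 ± 0.17). SAMD9 (ENSG00000205413, 93099513 to 93118023) had 39.8 ± 12.7 CPM against 104.9 ± 54.6 and was lower in 9 of 10 patients. EZH2 (-0.55 ± 0.34, adjusted p = 0.208), KMT2C (-0.29 ± 0.19, 0.238) and LUC7L2 (-0.39 ± 0.19, 0.112) did not pass edgeR's test. The CNOT4 call was lost under most alternatives (adjusted p from 0.0155 to 0.296), and the SBDS call without the patient block (0.119), the highest of its alternatives.

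Of the 19 named 7q genes measured, 4 were higher, 7 lower and 8 not called, with the same counts adjusted over the list alone. Of the 13 named 7p genes, 3 were higher, 1 lower and 9 not called, likewise. Neither list stood apart as a set (camera adjusted p = 0.523 and 0.215). Among all 275 tested 7q genes, 20 were higher and 111 lower, and among 139 7p genes 20 were higher and 44 lower. For 7q the camera p was 1.37e-06 at the preset correlation, and p = 0.291 with an estimated correlation, so this call was lost. Outside the named lists, the largest rises on chromosome 7 included TNS3 (4.59 ± 0.57) and AC092171.3 (5.21 ± 0.51), and the largest falls GIMAP4, a lymphocyte GTPase (-6.14 ± 0.42), and UPP1 (-3.83 ± 0.33). HOXA10-AS (4.52 ± 0.44) lies antisense to HOXA genes, and the use of strand in counting is not given in the sources used here. NCF1 (-3.52 ± 0.41) has near-identical pseudogenes and is uncertain.

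**Figure D3:**
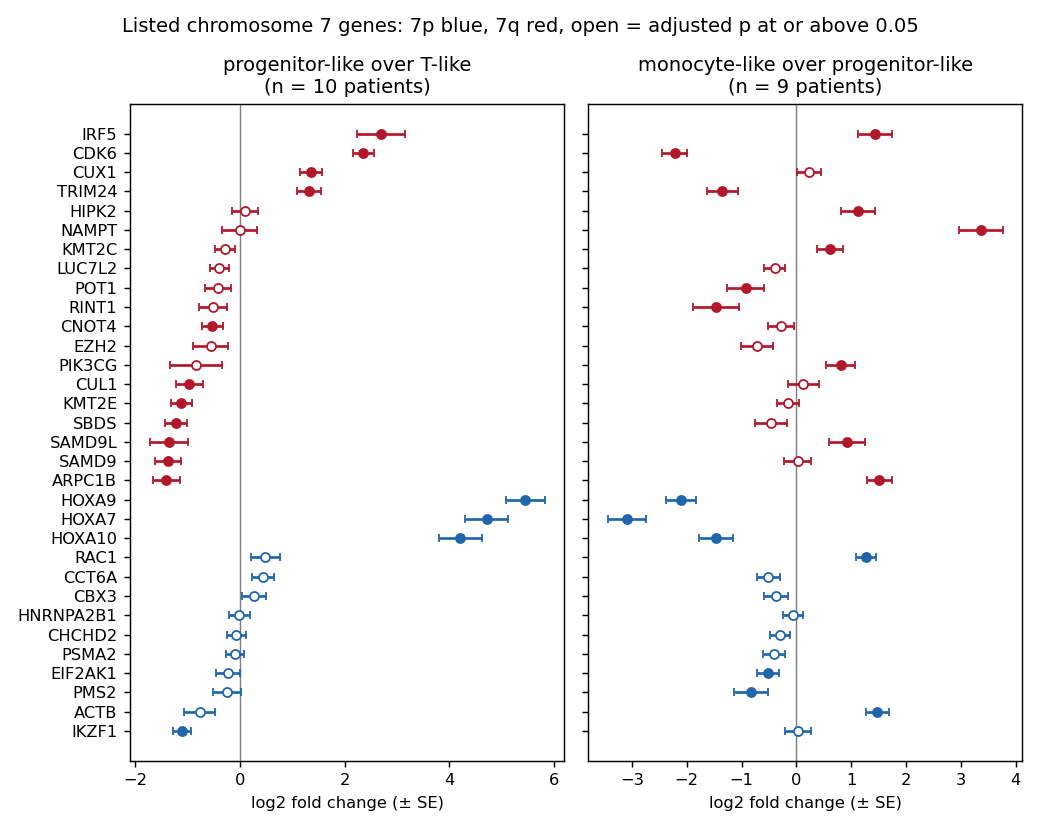
Log2 fold change ± SE of the listed chromosome 7 genes in progenitor-like over T-like cells (left, 10 patients) and monocyte-like over progenitor-like cells (right, 9 patients), with open points for genes that did not pass the adjusted threshold. HOXA9, HOXA7 and HOXA10 lie far right on the left side and left of 0 on the right side.

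Of 16 listed genes of the LSC17 leukaemic stem cell signature, taken without the X chromosome, 9 were tested. Of these, 8 were higher in progenitor-like than in T-like cells and none lower, MMRN1 (4.67 ± 0.42) and CDK6 among the higher ones. The class was itself named from stem and progenitor markers, so a rise of this list is not independent of the naming. The camera adjusted p was 6.03e-07, and adjusted p = 0.0793 with an estimated correlation. Of 9 surface targets, 5 were higher and 2 lower: FLT3, a growth factor receptor, by 5.00 ± 0.35, CD33 by 4.16 ± 0.44, CLEC12A by 3.27 ± 0.56, IL1RAP by 1.68 ± 0.28 and CD38 by 1.22 ± 0.36, while CD96 (-4.97 ± 0.40) and HAVCR2 (-1.46 ± 0.56) were lower. As a set they gave a camera adjusted p of 0.215. The HAVCR2 call was lost under most alternatives (adjusted p from 0.0219 to 0.130), and the CD38 call without the patient block and without 1 patient (from 0.00246 to 0.176 over the alternatives). In the BCL2 family 1 of 12 genes was higher, BCL2L2 (3.94 ± 0.50), and 4 were lower, among them the survival factor BCL2 (-1.29 ± 0.25) and the death-promoting BCL2L11 (-3.56 ± 0.43). Of 22 chromatin regulators 8 were higher, with DNMT3B (4.67 ± 0.49) and HDAC2 (1.64 ± 0.19) leading, and 2 lower, EED (-1.18 ± 0.19) and EZH1 (-0.75 ± 0.19). Of 6 MHC class II genes 4 were higher over all genes tested and 6 when adjusted over the list alone, with HLA-DRA at 3.16 ± 0.43 (camera adjusted p = 0.0896, and 0.00230 without 1 patient).

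Of 14 interferon response genes 5 were lower, with ISG15 at -1.65 ± 0.22 and MX2 at -1.30 ± 0.31 (camera adjusted p = 0.164). Cell cycle genes had 5 of 20 higher, with MCM4 (1.37 ± 0.29) and TYMS (1.66 ± 0.37), glycolysis genes 4 of 14 higher and 2 lower, with ENO1 at 1.61 ± 0.17 and SLC2A3 at -1.62 ± 0.32, and p53 targets 1 of 13 higher, GADD45A (1.47 ± 0.20), and 5 lower, DDB2 (-1.39 ± 0.23) among them. Immediate early and heat shock genes had 5 of 14 higher, led by EGR1 (3.31 ± 0.56), and 3 lower, led by JUNB (-2.31 ± 0.32). Oxidative phosphorylation (3 of 27 higher, 5 lower), proteasome (4 of 22 higher, 1 lower) and cytosolic ribosome genes (2 of 32 higher, 1 lower) had few members called. None of these lists passed camera. Without the low-count filter the interferon (camera adjusted p = 0.0116), MHC class II (0.0246) and chromatin regulator lists (0.0412) did. Adjusted over the list alone the counts were the same for interferon, oxidative phosphorylation, immediate early and p53 genes, and became 4 higher for the cell cycle, 5 higher and 3 lower for glycolysis, 3 higher for the proteasome and 1 higher for the ribosome.

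In all, edgeR called 2811 of 7968 genes outside markers and clustering genes, 1726 higher and 1085 lower in progenitor-like cells (n = 10 patients, 12423 and 3211 cells). On chromosome 7 it called 195 of 414, 40 higher and 155 lower. With markers and clustering genes, which differ by construction, 3392 of 8943 were called, 55.0% of them higher. Without the low-count filter this was 5558 genes, 69.1% of them higher.

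The listed HOXA genes that were tested were lower in monocyte-like than in progenitor-like cells, while HOXA3 and HOXA6 were not tested. HOXA7 (-3.09 ± 0.35), HOXA5 (-2.44 ± 0.41), HOXA9 (-2.11 ± 0.28) and HOXA10 (-1.47 ± 0.31) were lower, each in 9 of 9 patients, and so were CDK6 (-2.22 ± 0.23) and TRIM24 (-1.35 ± 0.28). NAMPT, an enzyme of NAD synthesis, was higher by 3.36 ± 0.40, the cytoskeletal genes ARPC1B, ACTB and RAC1 by 1.51 ± 0.22, 1.48 ± 0.22 and 1.27 ± 0.19, and IRF5 by 1.43 ± 0.30. Of 19 named 7q genes 7 were higher and 4 lower, and of 14 named 7p genes 2 were higher and 6 lower, with 5 and 7 lower when adjusted over the list alone. Neither list passed as a set (camera adjusted p = 0.589 and 0.219), but the 7p list did without the low-count filter (0.0313). Of all 269 tested 7q genes 42 were higher and 54 lower (camera p = 0.911), and of 153 7p genes 30 were higher and 38 lower (p = 0.564). The largest rises were FGL2 (7.44 ± 0.44), PILRA (5.76 ± 0.41) and CD36, a scavenger receptor (5.23 ± 0.43), and the largest falls GNAI1 (-3.31 ± 0.32) and MEST (-3.13 ± 0.44).

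Of 16 interferon response genes 11 were higher in monocyte-like than in progenitor-like cells and none lower, with IFIT2 at 2.38 ± 0.31 and MX2 at 2.10 ± 0.26 (camera adjusted p = 6.05e-06, adjusted p = 0.534 with an estimated correlation). Of 7 MHC class II genes 6 were higher, with HLA-DMB at 2.07 ± 0.28 and CD74 at 1.11 ± 0.26 (camera adjusted p = 0.00537, adjusted p = 0.649 with an estimated correlation). With classes from marker scores the median of this list was 0.60, against 1.22, and its call was lost (camera adjusted p = 0.125), as was that of CD74 (0.50, adjusted p = 0.167), both the highest p of the alternatives. Without 1 patient the median was 0.80 (camera adjusted p = 0.00890). Of 32 cytosolic ribosome genes 27 were lower, RPLP0 at -1.45 ± 0.24 (camera adjusted p = 1.20e-06, adjusted p = 0.649 with an estimated correlation), with a median of -0.91 that was -0.56 under the stricter cell filter. Of 22 cell cycle genes 15 were lower, TYMS at -2.69 ± 0.38 (camera adjusted p = 0.00101, adjusted p = 0.649 with an estimated correlation). Of 10 tested LSC17 genes 9 were lower, AKR1C3 at -2.72 ± 0.29 (camera adjusted p = 1.49e-06, adjusted p = 0.426 likewise). Adjusted over the list alone, 12 interferon, 6 MHC class II, 29 ribosome, 16 cell cycle and 9 LSC17 genes passed.

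In the BCL2 family 4 of 12 genes were higher, BCL2L11 by 3.87 ± 0.42, BCL2A1 by 3.28 ± 0.48, MCL1, a survival factor, by 1.53 ± 0.30 and BID by 1.04 ± 0.30, and BCL2 was lower (-0.97 ± 0.30). Over the alternatives the adjusted p ranged from 0.00112 to 0.0722 for BCL2, whose call was lost under the stricter cell filter, without the patient block and with at least 50 cells per class, and up to 0.0980 for BID, lost with at least 50 cells. Among 8 surface targets CLEC12A (3.11 ± 0.51) and HAVCR2 (2.51 ± 0.43) were higher and CD38 lower (-1.20 ± 0.27). Chromatin regulators had 3 of 22 higher, with TET2 at 1.20 ± 0.26, and 8 lower, with DNMT3B at -3.22 ± 0.44. The p53 targets had 2 of 14 higher, CDKN1A (3.66 ± 0.31) and MDM2 (0.80 ± 0.20), and 2 lower. Glycolysis (6 of 15 higher, 3 lower), immediate early and heat shock (6 of 16 higher, 3 lower), oxidative phosphorylation (7 of 27 higher, 6 over the list alone) and proteasome genes (2 of 22 higher, 1 lower) completed the lists. None of these passed camera, though oxidative phosphorylation did under the stricter cell filter (median 0.52 against 0.25, camera adjusted p = 0.00243) and without the low-count filter (0.00610), where immediate early and heat shock genes did too (0.0451). Apart from oxidative phosphorylation their counts were the same adjusted over the list alone. In all, edgeR called 3340 of 8382 genes outside markers and clustering genes, 1222 higher and 2118 lower (n = 9 patients, 2000 and 10504 cells), and 3980 of 9397 with them.

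On progenitor-like cells CD34, the stem and progenitor antigen, was higher than on T-like cells by 2.81 ± 1.86 (difference of centred log2 ratio, SD, n = 10), CD117 by 2.55 ± 1.60, CD33 by 2.22 ± 1.70, CD133 by 1.95 ± 1.76, CD123 by 1.39 ± 1.12 and CD13 by 1.12 ± 1.16, each in 10 of 10 patients. CD200, CD22, CD90, CD115 and CD14 were higher by 0.87, 0.69, 0.55, 0.52 and 0.17 in the permutation test, but edgeR on the summed tags called none of these, with adjusted p = 0.0706, 0.133, 0.0559, 0.334 and 0.539. In raw tags the rises of CD14 and CD115 did not hold. The mean of patients' medians was 22.9 in progenitor-like against 25.6 in T-like cells for CD14, and 7.27 against 7.36 for CD115 (n = 11 each). It was higher in progenitor-like cells for CD200 (13.5 against 11.6), CD22 (17.8 against 15.8) and CD90 (8.64 against 7.91). The T cell proteins CD3 (-3.53 ± 1.92) and CD2 (-3.22 ± 1.95) were lower, as were CD45 (-2.34 ± 0.46), CD7 (-1.79 ± 1.51), CD45RA (-1.65 ± 1.39), CD26 (-1.36 ± 1.40) and CD95 (-1.09 ± 0.95). In all 18 of 31 antibodies passed the permutation test after adjustment, 11 higher and 7 lower. With edgeR 13 passed, 6 higher and 7 lower, and all 13 were among the 18. The CD45RA call was lost with per-cell ratios (-0.94, adjusted p = 0.0865). The CD96 antibody did not pass (-0.21 ± 0.44, permutation p = 0.178), and its mean of patients' median tags was 16.7 in T-like and 20.1 in B-like cells. A centred ratio is relative to the other antibodies.

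Monocyte-like cells had more of the myeloid receptors CD11b (2.92 ± 1.71) and CD32 (2.70 ± 1.33), of CD45 (1.80 ± 0.41), CD16 (1.73 ± 1.77), CD14 (1.02 ± 1.30), CD95 (0.88 ± 0.69), CD13 (0.73 ± 0.57), CD47 (0.45 ± 0.29) and CD38 (0.45 ± 0.39) than progenitor-like cells (n = 9). Relative to the other antibodies they had less CD117 (-2.54 ± 1.78), CD34 (-2.44 ± 1.37), CD133 (-2.30 ± 1.73), CD25 (-1.24 ± 1.33), CD7 (-1.07 ± 0.87) and CD200 (-1.02 ± 0.87). CD115, the receptor of a monocyte growth factor, was also lower on this relative scale (-0.50 ± 0.59, lower in 9 of 9 patients), as were CD22, CD56, CD244, CD90, CD96, CD26 and CD3, by -0.69 to -0.36. In raw tags not all of these falls held. The mean of patients' medians was higher in monocyte-like (n = 9) than in progenitor-like cells (n = 11) for CD115 (9.67 against 7.27), CD244 (117 against 84.9), CD25, CD200, CD22, CD90, CD96, CD26 and CD3. It was lower for CD117 (8 against 43.3), CD34, CD133, CD7 and CD56. By exact permutation tests with adjustment 23 of 31 antibodies passed, 9 higher and 14 lower. With edgeR on the summed tags 20 passed, 6 higher and 14 lower, all among the 23, and CD14 (adjusted p = 0.0600), CD38 (0.104) and CD47 (0.0625) did not. Where a stricter cell filter or at least 50 cells per class left 6 patients, 0 antibodies passed the permutation test after adjustment. There 14 and 16 had an unadjusted p under 0.05, too few to pass over 31 at the smallest possible p of 0.0313.

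**Figure D4:**
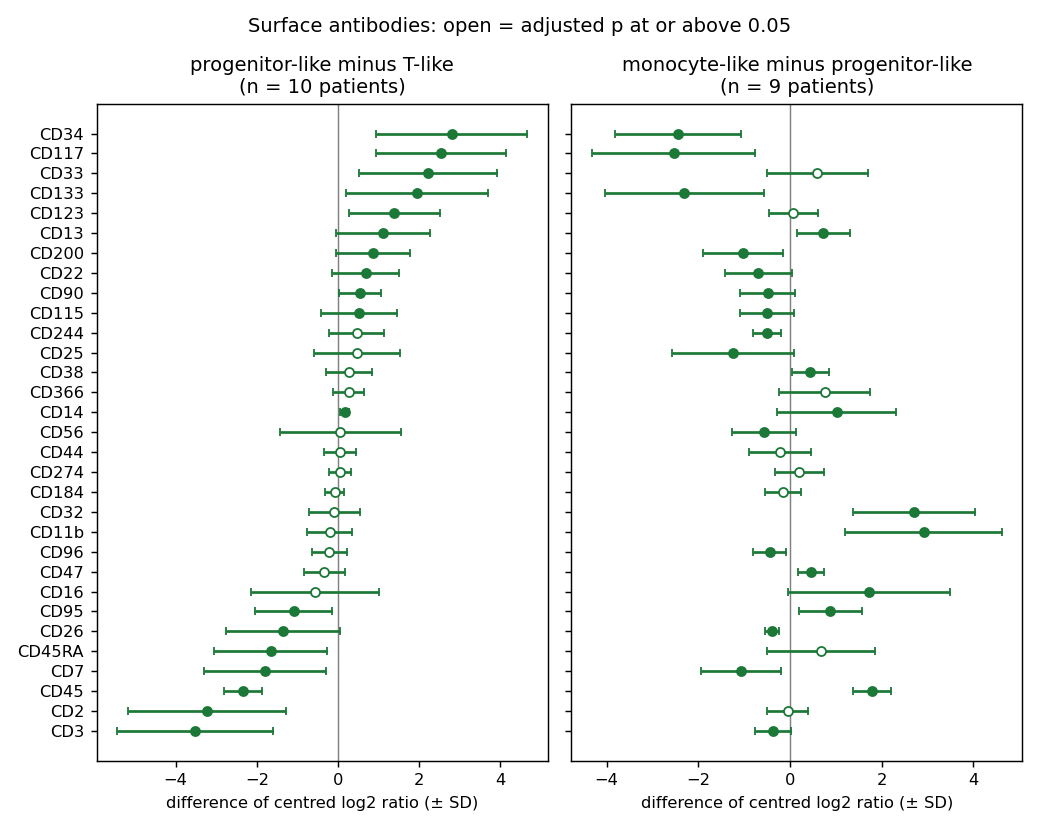
Difference of the centred log2 ratio of each antibody, mean ± SD over patients, for progenitor-like minus T-like cells (left, n = 10) and monocyte-like minus progenitor-like cells (right, n = 9), with open points for antibodies that did not pass adjustment. CD34 and CD117 lie above 2 on the left and below -2 on the right.

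Within progenitor-like cells, protein and RNA of the same gene rose together only weakly from cell to cell. The mean Spearman coefficient over patients was highest for CD44 (0.257 ± 0.174, n = 11), CD38 (0.207 ± 0.0947), CD7 (0.193 ± 0.223), CD117 (0.191 ± 0.118), CD34 (0.151 ± 0.116), CD133 (0.140 ± 0.112, n = 10) and CD33 (0.129 ± 0.0828). It was positive in 11 of 11 patients for CD44, CD38, CD117, CD34, CD33 and CD123. In all 13 of 30 pairs passed the permutation test after adjustment, each with a positive mean, and 15 had an unadjusted p under 0.05. With the antibody as the log of its share of all tags 11 passed, and CD200 (permutation, adjusted p = 0.479) and CD95 (0.153) did not. CD47, whose RNA was seen in 63.7% of cells, had 0.0345 ± 0.0969 (permutation p = 0.260). Over all kept cells 22 pairs passed, a count that includes differences between classes.

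No antibody passed the test of a correlation with the chromosome 7 share of progenitor-like cells. By permutation tests 0 of 31 passed after adjustment and 5 had an unadjusted p under 0.05. CD117 had the largest mean coefficient, -0.128 ± 0.140 (n = 11, p = 0.0127, adjusted p = 0.197). The same test for the other autosomes called a median of 0 antibodies and at most 11.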

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

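The tests for a patient standing apart were set in advance, and none in this part was chosen after the result was seen. Among 267 sets of values from 4 to 10 patients, 39 had a highest or lowest patient far from the others, where chance alone gives about 1 in 20. None of the 20 sets of chromosome 7 and arm values was among them, against 9 of 62 antibody sets and 30 of 185 gene sets. Sets share patients and are not independent, and no explanation was tested. The number given for each is the gap to the nearest patient as a share of the whole range.

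In progenitor-like against T-like cells (n = 10), the highest patient stood apart for the antibodies CD115 (0.617), CD200 (0.573), CD25 (0.522) and CD366 (0.501), and the lowest for CD16 (0.849), CD274 (0.686) and CD32 (0.610). For RNA the highest patient stood apart in POT1 (0.732), ATP5F1B (0.683), PMS2 (0.639), SLC2A3 (0.634), MCM4 (0.612), RINT1 (0.573), NAMPT (0.546), BID (0.531), EZH2 (0.520) and NCF1 (0.495), and the lowest in PIK3CG (0.647).

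In monocyte-like against progenitor-like cells (n = 9), the highest patient stood apart for the CD14 antibody (0.581) and for CD74 RNA (0.619), and the lowest for the CD25 antibody (0.528). For RNA the lowest patient stood apart in HOXA10 (0.772), PSMB5 (0.719), PMS2 (0.709), PFKP (0.679), HIPK2 (0.679), IFIT2 (0.678), CUL1 (0.666), TRIM24 (0.656), CD38 (0.651), EZH2 (0.596), SESN1 (0.580), SBDS (0.578), DNMT3A (0.562), FLT3 (0.524), KMT2C (0.521), PSMC4 (0.521), RINT1 (0.503) and PGAM1 (0.499).

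Outside the measurements used here, a median of 7.79% of the antibody tags of a library were assigned to no antibody.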

How the results depend on the processing

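Finer clustering, removal of more doublets, measures without ribosomal protein genes, libraries with most cells matched and shares by marker score were tried after the data had been seen, and the other alternatives before. For chromosome 7 the sides of the threshold below are those of the unadjusted permutation p. The cause of a change was not tested unless given. With 5 patients or fewer, as for monocyte-like cells with at least 50 cells and for NK-like cells with finer clustering or the stricter filter, the smallest exact permutation p is 0.0625 or more, so no call was possible.

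In progenitor-like cells the chromosome 7 value of -0.44 no longer passed under the stricter cell filter (-0.40), as a ratio of summed UMI shares (-0.34) and as that ratio without ribosomal protein genes (-0.28). Its mean was the 3rd lowest of 22 autosomes with both ratios. The 7q value became -0.33 and -0.27 with these ratios and lost its call with both, and the difference of the arms 0.023 with both, changing sign, and -0.081 with the more highly expressed genes. In monocyte-like cells the chromosome 7 value changed sign with summed shares (0.032) and lost its call with summed shares without ribosomal protein genes (-0.15), the stricter filter (-0.50), at least 50 cells (-0.50, n = 5) and highly expressed genes (-0.29); leaving out each patient gave -0.48 to -0.34, and the call was lost at -0.34 (n = 8, exact permutation p = 0.0625). Monocyte-like 7q gave -0.73 with at least 50 cells (n = 5, below 0 in 5 of 5 patients), -0.22 with highly expressed genes, -0.23 and -0.41 with the summed ratios and -0.62 with the stricter filter, none past the threshold. Their 7p value changed sign to 0.19 and 0.015 with the summed ratios, and the difference of arms passed with both (-0.43) but changed sign with highly expressed genes (0.094). Erythroid-like cells passed with summed shares (-0.84), these without ribosomal genes (-1.18), where chromosome 7 was only the 8th and 4th lowest of 22 autosomes, and without ribosomal genes alone (-0.26), but were at -0.047 with marker scores and -0.014 with highly expressed genes. Without each patient they ranged from -0.29, which passed (n = 9, exact permutation p = 0.0313), to -0.16. NK-like values changed sign with finer clustering (0.050), summed shares (0.065) and the stricter filter (0.0072), and B-like values with marker scores (-0.17) and the summed ratios (-0.079, -0.042), all without passing. With the summed ratios B-like 7p did pass (-0.17 and -0.14, permutation p = 0.0156 and 0.00781), as did the B-like difference of arms (0.20, permutation p = 0.00781 with both). No arm value of NK-like cells passed with them.

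For the share of low cells, NK-like cells changed sign from -10.6 points to 4.98 without thinning and 3.52 at 2500 UMIs. They also did so without ribosomal genes (1.88), where B-like cells passed with 4.52. That setting was thinned to 1000 UMIs. With ribosomal genes at 1000 UMIs, NK-like cells gave -12.2 and B-like cells 1.32 points. Erythroid-like cells at 2500 UMIs gave 68.6 points without passing (adjusted p = 0.0781, n = 7, exact permutation). Without the low-count filter 5558 genes were called in progenitor-like against T-like cells, and 4 lists against 1 (gaining interferon, MHC class II and chromatin regulators), and 8 lists against 5 in monocyte-like cells (gaining oxidative phosphorylation, immediate early and heat shock, and named 7p). The first list count was 2 with marker scores and 1 to 2 without each patient, the MHC class II list gained in both. Under the stricter cell filter the oxidative phosphorylation list gained a call in monocyte-like cells (0.52, camera adjusted p = 0.00243). No antibody passed in monocyte-like cells with the stricter filter (0) or at least 50 cells (0), against 23. On the summed tags of all patients compared edgeR called 20 against 23 in monocyte-like cells and 13 against 18 in progenitor-like cells, and 22 protein and RNA pairs passed over all kept cells against 13. By marker score plasma-like cells made up 2.43% and megakaryocyte-like cells 3.29%.

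Both classes of a pair come from 1 patient. Without this replicate block edgeR called 2515 genes in progenitor-like against T-like cells and 2737 in monocyte-like against progenitor-like cells, and chromosome 7 was at -0.41 and -0.48 in progenitor-like and monocyte-like cells. It changed the call for erythroid-like cells alone among classes, which passed unpaired (-0.26, permutation p = 0.0201). Some scalings moved the median of all genes by over 0.1: no low-count filter (0.15 and -0.13), and in monocyte-like cells DESeq2 (-0.10), marker scores (-0.12) and more doublets removed (-0.12).

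Of single values, 2013 for named genes, 480 for antibodies and 289 for lists kept their direction and side, 89, 60 and 1 lost their call, 38, 3 and 9 gained one, and 59, 15 and 31 changed sign. None of those that changed sign passed before or after. They follow as log2 values. Without the low-count filter the values were in progenitor-like against T-like cells MCL1 0.020, HNRNPA2B1 0.17, PSMA2 0.077, CHCHD2 0.11, NAMPT 0.17, the named 7p list 0.53, the oxidative phosphorylation list 0.017, the p53 target list 0.11 and in monocyte-like against progenitor-like cells IL1RAP -0.11, IKZF1 -0.12, SAMD9 -0.12, the named 7q list -0.058, the glycolysis list -0.036, the proteasome list -0.082, the p53 target list -0.060, the surface target list -0.0081. Without the patient block the values were in progenitor-like against T-like cells MCL1 0.018, HNRNPA2B1 0.034, KMT2C 0.014, PMAIP1 -0.084, the named 7p list 0.034, the proteasome list -0.068 and in monocyte-like against progenitor-like cells IL1RAP -0.032, IKZF1 -0.021. With the stricter cell filter the values were in progenitor-like against T-like cells MCL1 0.15, NAMPT 0.48, CD274 antibody -0.033, CD56 antibody -0.11 and in monocyte-like against progenitor-like cells IL1RAP -0.46, HNRNPA2B1 0.16, CD44 -0.064, the p53 target list -0.27, the surface target list -0.19, CD2 antibody 0.033. With library size alone the values were in progenitor-like against T-like cells HNRNPA2B1 0.071, CHCHD2 0.018, NAMPT 0.10, the named 7p list 0.071 and in monocyte-like against progenitor-like cells IL1RAP -0.0025. With DESeq2 the values were in progenitor-like against T-like cells HNRNPA2B1 0.035, NAMPT 0.13 and in monocyte-like against progenitor-like cells IL1RAP -0.025, IKZF1 -0.050, SAMD9 -0.071, CUL1 -0.00087. With doublets kept the values were in progenitor-like against T-like cells HNRNPA2B1 0.0044, NAMPT 0.017, the named 7p list 0.0044. With finer clustering the values were in progenitor-like against T-like cells HNRNPA2B1 0.013, PSMA2 0.034, CHCHD2 0.0060, NAMPT 0.050, HIPK2 -0.095, the named 7p list 0.034, CD56 antibody -0.12 and in monocyte-like against progenitor-like cells IKZF1 -0.033, CUL1 -0.11, the named 7q list -0.11, the proteasome list -0.00027, CD123 antibody -0.15. With classes from marker scores the values were in progenitor-like against T-like cells CHCHD2 0.046, NAMPT 0.048, the named 7p list 0.046 and in monocyte-like against progenitor-like cells IL1RAP -0.021, IKZF1 -0.18, SAMD9 -0.069, CUL1 -0.26, PMAIP1 -0.093, the named 7q list -0.23, the proteasome list -0.078, CD123 antibody -0.15. With more doublets removed the values were in progenitor-like against T-like cells NAMPT 0.0029 and in monocyte-like against progenitor-like cells IL1RAP -0.077, IKZF1 -0.090, SAMD9 -0.052, CUL1 -0.24, PMAIP1 -0.053, the named 7q list -0.23, the glycolysis list -0.10, the proteasome list -0.048, the p53 target list -0.044. With at least 50 cells the values were in monocyte-like against progenitor-like cells IL1RAP -0.067, HNRNPA2B1 0.058, CD2 antibody 0.14. With edgeR on antibody sums the values were in progenitor-like against T-like cells CD274 antibody -0.025, CD44 antibody -0.026, CD56 antibody -0.034 and in monocyte-like against progenitor-like cells CD123 antibody -0.066. With per-cell antibody ratios the values were in progenitor-like against T-like cells CD44 antibody -0.041 and in monocyte-like against progenitor-like cells CD123 antibody -0.038, CD2 antibody 0.090. With libraries of at least 60% matched cells the values were in progenitor-like against T-like cells CD44 antibody -0.030. Leaving out each patient in turn, the extremes of the count of calls gave HNRNPA2B1 from -0.058 to 0.016 (progenitor-like), HIPK2 from -0.0028 to 0.042 (progenitor-like), IKZF1 from -0.096 to -0.0057 (monocyte-like), SAMD9 from -0.16 to -0.012 (monocyte-like), the named 7p list from -0.050 to 0.016 (progenitor-like), the named 7q list from -0.16 to -0.012 (monocyte-like), the glycolysis list from -0.013 to 0.067 (monocyte-like), the proteasome list from -0.10 to -0.0034 (monocyte-like), the p53 target list from -0.018 to 0.034 (monocyte-like).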

Other observations

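The tests of the spread between patients, of the share of low 7p genes and of RNA detection were chosen after the results were seen, and the other tests in this part before. CD38, an ectoenzyme picked after its values were seen, had lower RNA in monocyte-like than in progenitor-like cells (-1.20 ± 0.27, SE, edgeR) and a protein difference of the other sign (0.45 ± 0.39, SD), which passed the permutation test but not edgeR (0.31, adjusted p = 0.104, from 0.0231 to 0.108 over the alternatives). Whether RNA and protein differ in their change was not tested, and the scales are not the same.

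Chromosome 7 expression was lower in progenitor-like than in T-like cells. Deeper counts in progenitor-like cells are argued against: with both classes of a patient thinned to the same total the mean was -0.42 ± 0.40 (n = 10, permutation p = 0.0195). The lower level on 7q was spread over most genes: 78.8% of the 66 genes lay below the autosomal median, against 33.3% to 67.0% on other autosomes. For 7p the share was 63.6%, within that range. The value is itself a median over genes, so these shares largely restate it. They are no separate test of whether a few strongly changed genes gave it. The values argue against a difference between the cell types of 1 size in all patients, since they ran from -0.92 to 0.08. Their SD between patients of 0.387 exceeded that of the other autosomes (median 0.0945) except the highest, 0.427. A difference between the cell types that varies between patients, as on that autosome, therefore stays open. Loss of chromosome 7 material in part of the cells may contribute, but the labels give no patient without an abnormality, and this was not tested.

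The large share of erythroid-like cells that were low in chromosome 7 may come from haemoglobin genes taking most of the counts. Without these genes the difference from T-like cells was 19.5 ± 37.7 points (n = 7, exact permutation p = 0.313), 31.4% against 11.9%. With them it was 69.8 points (n = 8). The value without these genes rests on 3196 erythroid-like cells, and the value with them on 6426. The fall therefore mixes removal of the genes with a change in the cells compared. How much each gave was not tested. HBB RNA was seen in 61.1% of T-like and 68.0% of progenitor-like cells as well, as free RNA in droplets would give.

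The weak correlation of protein and RNA within progenitor-like cells may partly reflect RNA that is detected in few cells. Over 30 antibodies the mean correlation rose with the share of cells with the RNA (Spearman rho = 0.663, Pearson r = 0.594). It also rose with the antibody's own count (rho = 0.538), so detection of either molecule remains open, and no biological explanation was tested.

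The classes were made by clustering the same cells, so that real labels call more genes than swapped ones was fixed by the design, and the following counts do not decide whether chance gave the calls. With the 2 classes swapped within patients in 50 labellings, the real one included, 1 gave as many genes as the real 3392 for progenitor-like against T-like cells, and the highest other gave 885. For monocyte-like against progenitor-like cells 1 of 50 gave the real 3980, and the highest other gave 0.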
